A study of Mus musculus with 8 samples.

How the data were processed

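Single mouse EPS-blastoids were collected at day 5 of culture, lysed in TRIzol and turned into Smart-seq2 libraries that were read as pairs of 150 bp, per the labels. The culture mixed 25% trophoblast stem cell medium, 25% N2B27 and 50% KSOM with 12.5 ng/ml FGF4, 5 ng/ml BMP4, 3 µM CHIR99021 and 0.5 µM A83-01, per the labels' protocols. The labels give 8 samples of 1 group, replicates 1 to 8, called blastoids 1 to 8 here. The labels say that each sample is an individual blastoid, but not whether these came from separate cultures. P-values of correlations and score fits therefore measure only the spread between these 8 structures. Those from random gene lists compare genes with other genes within these 8 libraries and do not measure that spread.

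The deposited files hold 1 table per blastoid with 134643 transcripts, the same in each. Reads were trimmed with cutadapt 1.9, aligned to GRCm38 with HISAT2 2.1.0 and quantified with StringTie 1.3.4d, per the submitters' processing notes, which also name CASAVA. Each table gives, per the file headers, the mean coverage of each transcript (a signal not scaled by depth) and its FPKM, made by the authors with StringTie per kilobase of transcript and relative to the mapped total. Within a file, coverage divided by FPKM is a constant equal to the mapped bases in gigabases (Gb), which gave the depth of each library, 9.35 to 14.5 Gb. Of these bases, 89.2% to 90.3% lay on listed transcripts. StringTie values are estimates rather than whole reads, so no counting interval was given, and PCR copies could not be told from molecules. Any other filter used by the authors is not given in the sources used here. StringTie can split reads between near-identical copies, so values of genes with such copies (ribosomal protein and mitochondrial genes, Ftl1) are uncertain, as are those of overlapping genes.

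FPKM was summed per gene symbol and rescaled to 1000000 per blastoid (TPM). Of 53330 gene IDs, 53145 matched the reference names, and the other symbols were used as the files give them. For 123 symbols with several IDs, values were summed. Coordinates are those of the files on GRCm38. Tests used log2(TPM + 1), with pseudocount 1, of the 11097 genes with a mean of 1 TPM or more. On that scale changes of low genes are understated. No count test was used, since the files hold no counts.

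The tests, the gene lists and the rule for named genes were fixed before the data were examined. The 31 lists covered the lineages (epiblast, trophectoderm, primitive, parietal and visceral endoderm, extraembryonic ectoderm, differentiated trophoblast, primitive streak and mesoderm, formative and primed pluripotency, two-cell-like, germline, oocyte), other cell types (fibroblast, neural, blood and endothelium), junction and cavity genes, targets of WNT, BMP, FGF-ERK, NODAL, YAP and p53, hypoxia and glycolysis, the integrated stress response, immediate early genes, G2/M and S phase, mitochondrial, ribosomal protein and imprinted genes, and a sex check. The lists were drawn from general knowledge and not from these samples, and some genes stand in more than 1 list. Members at 1 TPM or more were counted per list. The named genes were 15 lineage regulators and keratins, the 3 members with the highest mean of each lineage list, the 20 genes of mean 10 TPM or more with the highest residual SD, the 10 genes with the highest mean and the leading transcript of each of 8 genes. Score fits added none, as fewer than 5 genes passed. Other members given as examples of a list were chosen after their values were seen. Spink3 is listed under the symbol Spink1.

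Residual SD is the SD of log2(TPM + 1) over the 8 blastoids minus its lowess trend (fraction 0.3) on the mean. For 20 lists with at least 4 members at a mean of 1 TPM, the median residual SD (two-sided) and the mean pairwise Pearson correlation (one-sided, greater) were compared with 10000 random lists of the same size, drawn within a window of 200 genes of like mean. The smallest p these can give is 0.0002 for the residual SD and 0.0001 for the correlation. Scores are the mean z-score of the members, with shared members left out of both lists. Correlations of scores and genes were tested with all 40320 orders of the 8 blastoids (exact, two-sided). Genes following a score were tested with limma 3.58.1 (trend) in R 4.3.3, with members of the score left out, and the fit was repeated on 100 permuted scores. All families were adjusted by Benjamini-Hochberg with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

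The steps were tested on simulated data, with each gene's 8 values shuffled on their own and, for the exact tests, random normal values. The shuffle removed any pattern shared across a library, so these rates need not hold for the real data. With nothing planted, 4% of 200 lists of 13 members passed the covariation step at a p under 0.05, 5% of lists passed the variability step and 5.4% of 500 exact tests passed. A shared factor of weight 0.4 was found in 64% of lists and one of weight 0.6 in 100%. For genes following a score, limma found 0%, 6%, 44% and 100% of 50 planted genes at slopes of 1, 2, 4 and 8 log2 units per SD. Each slope was added to the gene's full shuffled spread. Of the 11097 genes fitted, those with no planted slope gave 0 false calls.

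The alternatives chosen beforehand were a pseudocount of 0.1, FPKM as deposited, median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, no filter or a filter at a mean of 5 TPM, removal of the trend on mapped bases, scores without z-scoring, rank correlation, limma without its trend, a detection threshold of 5 TPM, transcripts over 5% of their gene only, leaving out the 2 blastoids farthest from the median score, and leaving out each blastoid in turn. Chosen after seeing the data were removal of the trend on the number of genes held, values under 1 TPM set to 0, leaving out blastoids 1 and 2, removing the mean of each library pair (tested over the 16 swaps within pairs, for correlations and covariation), comparing the median SD itself with matched lists, genes at 1 TPM or more in all 8, and setting to 0 values under 0.2% of the partner library's value.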

Results

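RNA was measured in 8 mouse blastoids, blastocyst-like structures grown in culture from extended pluripotent stem (EPS) cells, which are stem cells held in conditions meant to give them both embryonic and extraembryonic potential. The blastocyst has an outer trophectoderm, which forms the placenta, and an inner mass that parts into the epiblast, which forms the embryo proper, and the primitive endoderm, which lines the yolk sac. About 5 cells were seeded per microwell in a mixed medium with FGF4, BMP4, an activator of WNT signalling (CHIR99021) and an inhibitor of TGF-beta family receptors (A83-01). Each library was made from a single blastoid at day 5 with Smart-seq2, a method that copies full-length transcripts from very little RNA. The 8 blastoids formed 1 group. The series set out to compare blastoids with natural blastocysts, which were not analysed here, so the question addressed was which lineage genes each blastoid expressed and how far single blastoids differed.

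The libraries were of similar depth but differed widely in the number of genes they held. Mapped bases were 11.8, 12.5, 14.5, 13.5, 14.5, 13.2, 9.62 and 9.35 gigabases (Gb) in blastoids 1 to 8, a 1.55-fold range. At these depths a transcript of 1 kb at 1 FPKM stood for 31.2 to 48.3 read pairs. Genes at 1 TPM or more (FPKM rescaled to the same total in every library) numbered 3360, 2754, 4152, 6987, 7436, 9164, 4937 and 5424 in the same order, a 3.33-fold range. This number did not follow the mapped bases (Pearson r = 0.283, exact permutation p = 0.488; Spearman rho = 0.238, exact permutation p = 0.582; r = 0.438 without blastoids 7 and 8). Of 53203 gene symbols, 12302 reached 1 TPM in at least 1 blastoid, 1118 in all 8 and 3234 in exactly 1. Genes that every cell uses were among those missing: of 14 core subunits of the proteasome, which degrades proteins, 3 were under 1 TPM in blastoid 1, 5 in blastoid 2 and 2 in blastoid 3. A value of 0 is therefore given below only as listed at 0, and means with SD are given only for genes at 1 TPM or more in all 8. In the 7 libraries with at least 5 genes at 100 TPM or more that were under 1 TPM in every other, these genes left traces of 2.75 to 9.24 per 10000 in a partner library (1 with 2, 3 with 4, 5 with 6, 7 with 8), so values under 1 TPM carry little weight. Blastoid 6 had 1 such gene, with no trace in blastoid 5.

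**Figure D1:**
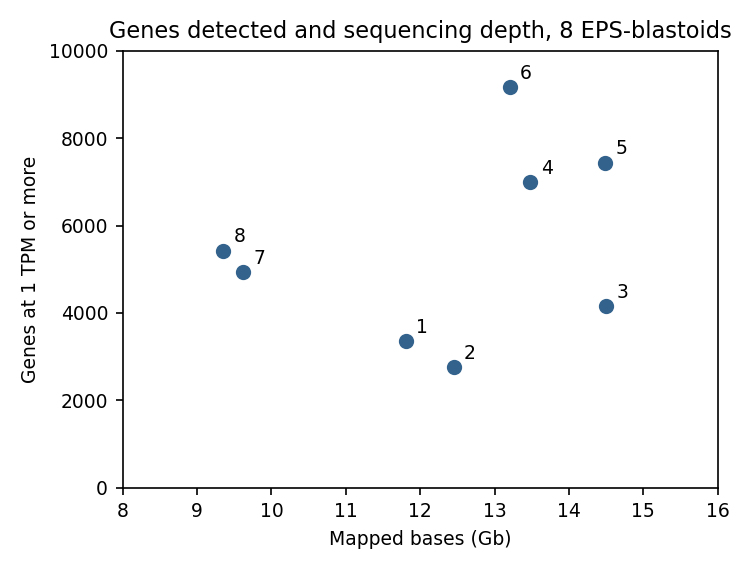
Mapped bases in Gb (x axis) against genes at 1 TPM or more (y axis), 1 point per blastoid, numbered. Blastoid 6 held 9164 genes and blastoid 2 held 2754 at mapped bases of 13.2 and 12.5 Gb.

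The keratins of trophectoderm epithelium Krt8 and Krt18 were high in all 8 blastoids, while other trophectoderm genes were patchier. Krt8 and Krt18, which encode the keratin pair of simple epithelia, averaged 3034 ± 979 and 4456 ± 1490 TPM (SD, n = 8), with ranges of 2014 to 4504 and 1974 to 6493. On GRCm38 both lie on chromosome 15, Krt8 (ENSMUSG00000049382) at 101996698 to 102004482 and Krt18 (ENSMUSG00000023043) at 102028180 to 102032027. Tacstd2, a cell surface glycoprotein of epithelia and trophoblast, averaged 244 ± 149 TPM. Krt19, another keratin, ranged from listed at 0 in blastoid 2 to 651 TPM in blastoid 7. Of the trophoblast transcription factors, Gata3 reached 6.34 to 148 TPM in blastoids 3 to 8 and was listed at 0 in blastoids 1 and 2. Gata2 reached 79.8 to 250 TPM in 5 blastoids, and Tfap2c reached 30.2 to 361 TPM in 7 and was listed at 0 in blastoid 8. Cdx2 and Eomes, transcription factors of early trophoblast and its stem cells, were listed at 0 in all 8 libraries, and Elf5 stayed under 1 TPM. Of the 18 trophectoderm genes, 3 reached 1 TPM in all 8 blastoids, 9 in at least 4 and 13 in at least 1, and each blastoid held 5 to 11 of them.

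Epiblast markers were carried by all blastoids in different subsets. Dppa5a, an RNA-binding protein abundant in pluripotent cells (ENSMUSG00000060461, chromosome 9, 78367052 to 78368177), averaged 5878 ± 5816 TPM and spanned 400 in blastoid 7 to 17694 in blastoid 2, a 44.2-fold range. Pou5f1, the OCT4 transcription factor of pluripotency, was at 1001 TPM in blastoid 2, 15.5 to 249 in blastoids 4 to 8, 0.987 in blastoid 1 and listed at 0 in blastoid 3. Nanog and Sox2, which act with OCT4, each passed 1 TPM in 1 library, Nanog at 43.2 TPM in blastoid 5 and Sox2 at 37.7 TPM in blastoid 8. Utf1, a chromatin protein of pluripotent cells, reached 67.3 to 493 TPM in 7 blastoids and was at 0.125 in blastoid 2. Tdh, a threonine-degrading enzyme that mouse pluripotent cells rely on, reached 81.5 to 738 TPM in 6. Zfp42, a zinc finger protein of naive pluripotency, reached 33.8 to 337 TPM in 4. Of the 19 epiblast genes, 1 reached 1 TPM in all 8 blastoids, 7 in at least 4 and 17 in at least 1. The members per blastoid numbered 9, 4, 4, 7, 14, 14, 3 and 7. Blastoids 5 and 6, with 14 each, also held the most genes (7436 and 9164), so the counts may partly follow detection. Blastoid 1, however, held 9 with only 3360 genes.

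The named primitive endoderm regulators were listed at 0 in most libraries, whereas Apoe and Serpinh1 were present in all 8. Apoe, a lipid carrier, averaged 2090 ± 1411 TPM (183 to 4558) and Serpinh1, a collagen chaperone, averaged 477 ± 332 TPM (83.4 to 1151). Apoe and the epiblast gene Dppa5a were both highest in blastoid 2 and both lowest in blastoids 4 and 7, so Apoe alone does not show this lineage. Gata6, a transcription factor that starts the primitive endoderm programme (chromosome 18, 11052510 to 11085635), reached 28.5 TPM in blastoid 8 and was listed at 0 in the other 7. Pdgfra, a growth factor receptor that marks this lineage, reached 156 TPM in blastoid 2 and did not pass 1 TPM elsewhere. The water channel gene Aqp8 reached 604 TPM in blastoid 2 and 626 TPM in blastoid 8. Gata4 and Sox17, further regulators of the lineage, were listed at 0 in all 8. Of the 22 primitive endoderm genes, 2 reached 1 TPM in all 8 blastoids, 6 in at least 4 and 13 in at least 1, with 10 of them in blastoid 8 and 4 to 7 in each of the others. Among parietal endoderm genes, Sparc, a matrix protein, averaged 583 ± 515 TPM, Srgn, a proteoglycan core, reached 619 TPM in blastoid 8, and Nid1, a basement membrane protein, reached 30.9 to 62.8 TPM in 3 blastoids. That list had 1 of 9 genes at 1 TPM in all 8 blastoids and 7 in at least 1. Of 11 visceral endoderm genes, 5 reached 1 TPM anywhere. Ttr, which carries thyroid hormone, was at 120 TPM and Apoa2, an apolipoprotein, at 116 TPM in blastoid 8, and Trf, which carries iron, was at 198 TPM in blastoid 1.

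**Figure D2:**
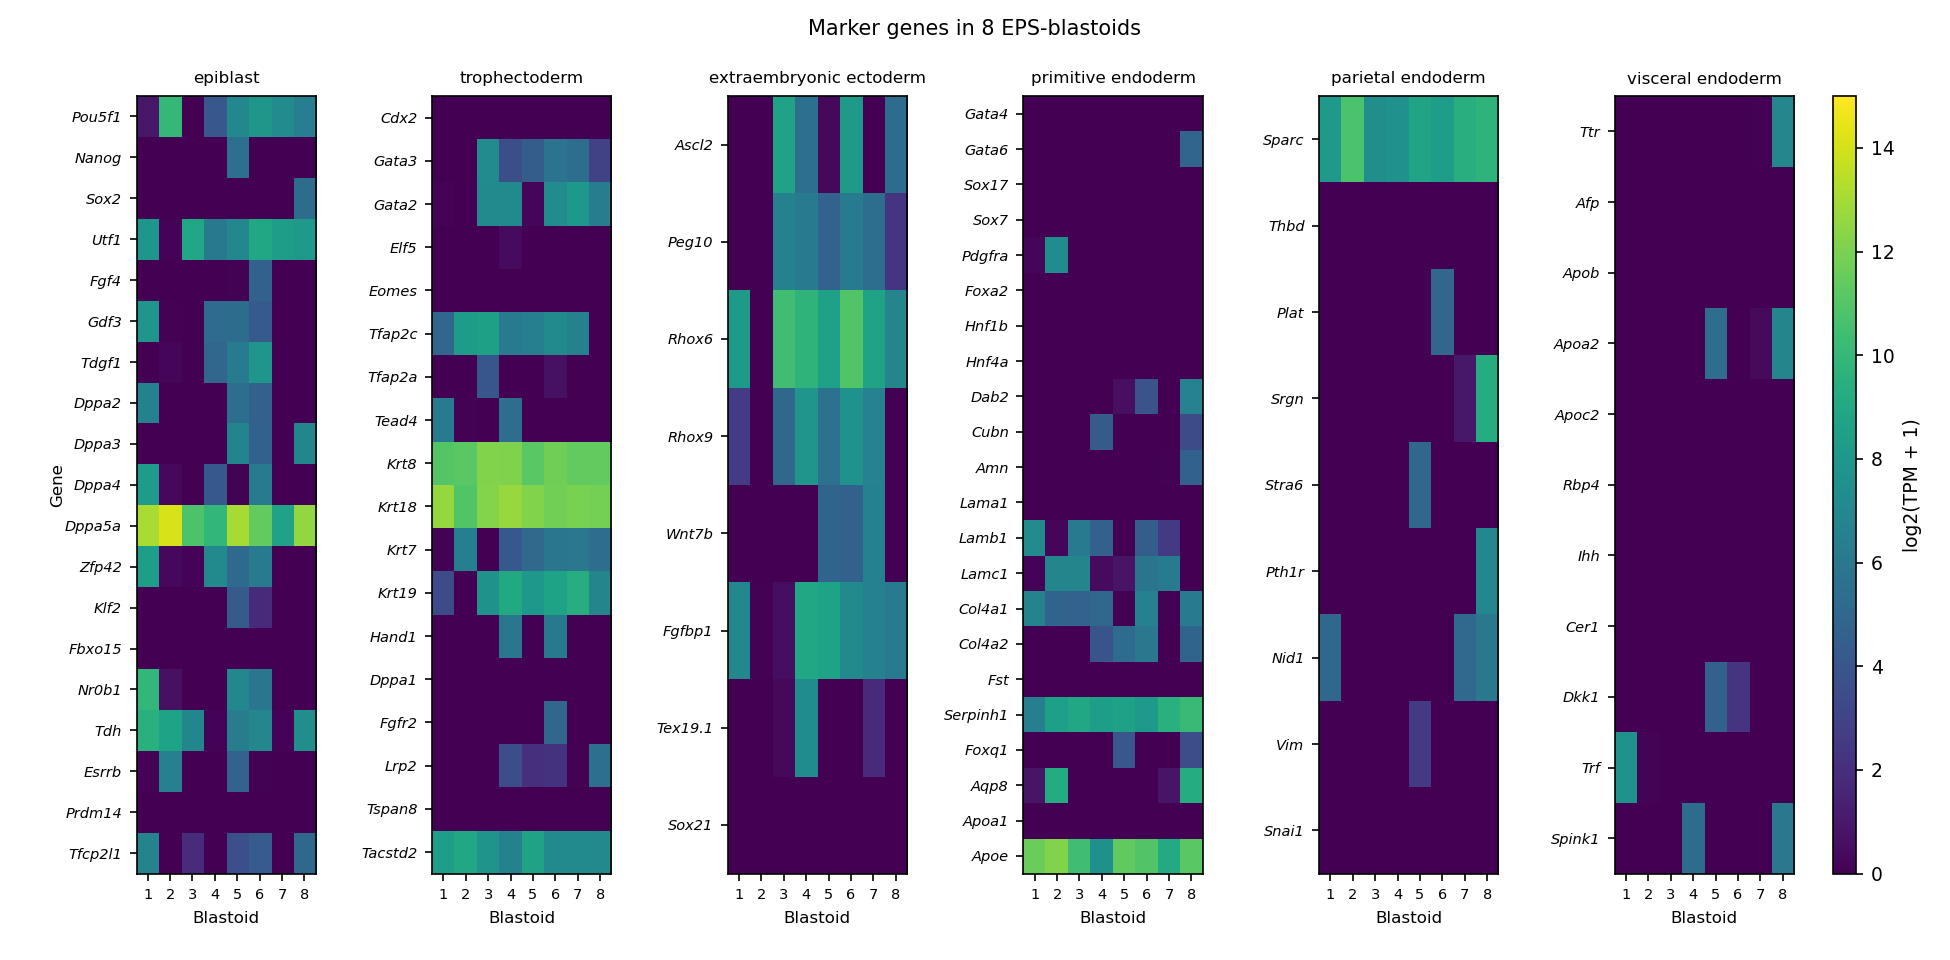
Level of each lineage gene (vertical axis) in each of the 8 blastoids (horizontal axis), with colour giving log2(TPM + 1). Krt8, Krt18 and Dppa5a are high in all 8, whereas Gata6, Ttr and Srgn reach 1 TPM only in blastoid 8.

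Rhox6 and Cdkn1c, genes of the placenta, were high in 7 of 8 blastoids but not in blastoid 2, a library that also lacked 29.4% of the 1584 genes held by all 7 others. Rhox6, a homeobox gene, reached 112 to 1980 TPM in 7 blastoids and was listed at 0 in blastoid 2. Fgfbp1, which releases FGF from the matrix, reached 70.6 to 511 TPM in 6. Ascl2, a transcription factor needed for the junctional zone of the placenta, reached 36.7 to 407 TPM in 4. Of 8 extraembryonic ectoderm genes, none reached 1 TPM in all 8 blastoids, 5 did in at least 4 and 7 in at least 1, and blastoid 1 held 3 of them and blastoid 2 held 0. Cdkn1c, an imprinted cell cycle inhibitor of trophoblast, reached 254 to 1358 TPM in 7 blastoids, and Plac1, a placental surface protein, reached 42.9 to 822 TPM in 6. Flt1, a VEGF receptor, reached 13 to 40.8 TPM in blastoids 6, 7 and 8. These were the 3 of 16 differentiated trophoblast genes that reached 1 TPM, and no prolactin-family gene did so.

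Markers of other cell types were sparse, and genes of formative and primed pluripotency were seen mainly through Dnmt3a and Dnmt3b. Primitive streak and mesoderm genes reached 1 TPM in 2.38% of their gene-by-library values (4 of 21 genes). T, the mesoderm regulator brachyury, was listed at 0 in all 8. The signalling genes Fgf8 and Wnt3 were at 29.7 TPM in blastoid 5 and 10.4 TPM in blastoid 6, and Gsc, an organiser homeobox gene, was at 23.2 TPM in blastoid 6. For genes of formative and primed pluripotency the share was 13.6% (4 of 11 genes). The DNA methyltransferase genes Dnmt3a and Dnmt3b led that list, at 16.1 to 469 TPM in 6 blastoids and 13.9 to 153 TPM in 4. Fgf5, Otx2, Sox3, Fgf15, Zic5 and Foxd3 of that list were listed at 0 in all 8, and Pou3f1 stayed under 1 TPM. Sall2, a zinc finger gene of that list, was at 19.2 TPM in blastoid 4. The share was 0.893% for genes of the two-cell-like state, 4.17% for germline genes and 2.5% for oocyte genes. It was 1.67% for fibroblast genes and 0% for the 10 blood and endothelial genes, and 1 of 10 neural genes reached 1 TPM, in 1 library. Over all gene symbols the share was 10.4%.

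Epithelial junction and cavity genes were widely expressed. Cldn4, a tight junction claudin, averaged 1755 ± 551 TPM and Cgn, which links junctions to the cytoskeleton, averaged 99.8 ± 45.3 TPM (n = 8). F11r, a junction adhesion molecule, ranged from 1.92 TPM in blastoid 1 to 546 in blastoid 3. Epcam, an epithelial adhesion protein, reached 72.5 to 534 TPM in 7 blastoids and was listed at 0 in blastoid 2. Of the 22 genes, 3 reached 1 TPM in all 8 blastoids, 14 in at least 4 and 20 in at least 1.

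The most abundant transcripts were those of ferritin, mitochondrial genes and the cytoskeleton. Ftl1, the ferritin light chain, averaged 14975 ± 4290 TPM. The predicted small gene Gm22133 averaged 22182 ± 6313 TPM, but it lies within the Ftl1 locus on chromosome 7, so their reads cannot be told apart. mt-Cytb, of the respiratory chain, and mt-Atp6, of the ATP synthase, averaged 18370 ± 4664 and 12852 ± 3039 TPM. Gm10925, listed on chromosome 1 at 13161 ± 3091 TPM, had values close to those of mt-Atp6 and lies in a nuclear copy of mitochondrial DNA, so their reads cannot be told apart either. Actb (beta-actin) averaged 7777 ± 1179, mt-Atp8 6568 ± 1497, the ubiquitin gene Ubb 6057 ± 1422 and mt-Co1 5010 ± 1105 TPM, and Dppa5a completed the 10 highest. Ribosomal protein genes reached 1 TPM in 99.2% of their values, and 14 of 15 did so in all 8 blastoids.

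Pairs of blastoids were alike in the genes that all 8 held and unlike in which other genes they held. Across 11097 genes with a mean of 1 TPM or more, Pearson's correlation of log2(TPM + 1) had a median of 0.467 over the 28 pairs, from 0.370 for blastoids 2 and 7 to 0.580 for 4 and 6. Over the 1118 genes at 1 TPM or more in all 8 blastoids, a set chosen after the data were seen, the median was 0.882, from 0.745 for blastoids 1 and 2 to 0.955 for 5 and 6. Spearman's correlation had a median of 0.487 and was highest for blastoids 1 and 2, at 0.792. Next came 3 and 4 (0.685), 7 and 8 (0.659) and 5 and 6 (0.615), the other partner libraries named above. This measure also ranks values under 1 TPM, of which partners share traces, so it does not by itself show that those blastoids were alike. These correlations run across genes, which are not independent replicates. The share of genes held in common, as the Jaccard index, had a median of 0.404.

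Of 20 lists, 2 passed as more variable between blastoids than other genes at the same level, and neither call held when the SD was compared without its trend on level. The 17 epiblast genes tested had a median residual SD of 0.48 log2 units around the trend of SD on mean level, against 0.18 for random lists matched on level (adjusted p = 0.0180 over 20 lists, permutation of list membership). This call was lost as the residual SD fell to 0.33 without blastoid 2 (adjusted p = 0.322) and to 0.31 without blastoids 1 and 2 (0.342), and at a residual SD nearer to the value with all 8 without blastoid 3 (0.46, adjusted p = 0.0600) and blastoid 4 (0.40, 0.0570). It was also lost when the SD itself, a median of 2.92 against 2.61, was compared with matched lists, a test chosen after the data were seen (0.350). The 9 genes of the mitochondrial genome passed too (median residual SD of 0.69 against -0.07, adjusted p = 0.0180), but this is not evidence of a wide spread, because the trend fell below 0 at the highest levels, for 5 of these 9 genes and 25 of all 11097. Their median SD was 0.40, the lowest of the 20 lists and below the 0.57 of matched lists (adjusted p = 0.347). The other 18 lists did not pass, including trophectoderm (adjusted p = 0.987), primitive endoderm (0.929), extraembryonic ectoderm (0.597) and hypoxia and glycolysis (0.135), of which the last passed with a pseudocount of 0.1 (0.0293) and with median-of-ratios scaling (0.0440). With the SD itself, 0 of 20 lists passed.

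The 20 single genes that varied most for their level were mainly abundant genes missing from 1 or 2 libraries. Phlda2, an imprinted gene that restrains placental growth, led with 859 to 4117 TPM in 7 blastoids and 0.758 in blastoid 2. Rhox6, Arpc2 (actin branching), Slc2a1 (a glucose transporter), Chchd2 (mitochondria), Prr13, Tubb6 (a tubulin), Aprt (purine salvage), Anxa1 (membrane binding) and Eif3k (translation initiation) were likewise under 1 TPM in blastoid 2. Swi5, of DNA repair, and Psmb3, a proteasome subunit, were at 1.06 and 1.16 TPM there. Atp5g1, of the ATP synthase, and Lamp1, of the lysosome, were at 0.105 and 0.771 TPM in blastoid 1 and reached 600 to 1438 and 520 to 1763 TPM elsewhere. Hn1, Cldn3 and Plp2 were under 1 TPM in blastoids 1 and 2. The metallothionein gene Mt1 was under 1 TPM in blastoids 2 and 8, and Anxa5 was listed at 0 in blastoid 3. Dppa5a alone of these 20 stayed above 100 TPM in all 8. Its residual (1.97) exceeded its SD (1.84), since the trend was below 0 there, so its rank is overstated.

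Mitochondrial genes rose and fell together between blastoids, and genes of hypoxia and glycolysis did so through blastoid 2. The mean pairwise correlation of the 9 mitochondrial genes was 0.497, against a median of 0.003 in matched random lists (adjusted p = 0.00200 over 20 lists, permutation of list membership). Their summed share of TPM averaged 4.79 ± 1.02%. The 13 hypoxia and glycolysis genes had a mean correlation of 0.248 against 0.031 (adjusted p = 0.0210), which fell to 0.025 without blastoid 2 (adjusted p = 0.713). It also missed the threshold with FPKM as deposited (adjusted p = 0.0610), with no filter on level (0.0814), with rank correlation (0.364) and without blastoids 1 and 2 (0.505). Pgk1 and Bnip3 of that list, a glycolytic enzyme and a mitophagy receptor, reached 282 to 919 and 176 to 682 TPM in 7 blastoids and were at 0.358 and 0.203 in blastoid 2. Ldha (1536 ± 433 TPM), Aldoa (2152 ± 525) and Eno1 (2798 ± 529), all of glycolysis, were present in all 8. Epiblast genes had a mean correlation of 0.227 and did not pass (adjusted p = 0.25), but passed with rank correlation (0.0413), once the trend on the number of genes held was removed (0.00100) and without blastoids 1 and 2 (0.01). Extraembryonic ectoderm genes, at 0.387, did not pass either (adjusted p = 0.193) and did with rank correlation (0.0310). Primitive endoderm genes, at 0.115 (adjusted p = 0.577), passed only with the trend removed (0.0240). Parietal endoderm genes, at 0.113 (adjusted p = 0.577), passed only with a filter of 5 TPM (0.0228), and trophectoderm genes, at 0.078 (adjusted p = 0.577), did not pass.

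The trophectoderm and extraembryonic ectoderm scores rose together over the 8 blastoids, a relation that missed the threshold in 8 of the 20 alternatives whose test could pass it, always in the same direction. Scores were the mean z-score of a list's genes, and 11 of the 20 planned pairs of lists could be scored. Adjusted p-values are over these 11, which is less strict than the planned adjustment over 20. The trophectoderm and extraembryonic ectoderm scores had r = 0.904 (exact permutation p = 0.00206, adjusted p = 0.0226 over 11) and rho = 0.905 (exact p = 0.00456, adjusted 0.0502), above 97.8% of random pairs of matched lists, whose median r was 0.561. Without blastoids 4 and 6, farthest from the median, r was 0.826 (exact p = 0.0431) and the relation no longer passed (adjusted p = 0.474 over 11). The adjusted p rose above 0.05 with little change in r without blastoid 2 (r = 0.915, adjusted p = 0.0720), 4 (0.881, 0.0938), 6 (0.896, 0.0698) or 8 (0.864, 0.107), without blastoids 1 and 2 (0.925, 0.0764) and with median-of-ratios scaling (0.848, 0.0805). With the trend on the number of genes held removed, r was 0.747 (adjusted p = 0.259). The exact p treats the 8 blastoids as exchangeable and does not allow for the positive r of random list pairs. The percentile among those pairs was not adjusted over the 11. With the mean of each library pair removed, the scores differed in the same direction in 4 of 4 pairs (r = 0.738, exact p = 0.125, the smallest that 16 swaps within pairs can give).

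No trade-off between the 3 founding lineages passed the exact test, although all 3 correlations lay below those of nearly all random list pairs. The epiblast and trophectoderm scores had r = -0.0303 (exact permutation p = 0.94; rho = -0.119, exact p = 0.793), with r = -0.544 without blastoids 5 and 6. The epiblast and primitive endoderm scores had r = 0.0768 (exact p = 0.893; rho = 0.286, exact p = 0.501), with 0.242 without the same 2. The trophectoderm and primitive endoderm scores had r = -0.199 (exact p = 0.693; rho = -0.167, exact p = 0.703), with -0.234 without blastoids 4 and 6. The adjusted p-values were 0.94, 0.94 and 0.847. All 3 lay in the lowest 2% of random list pairs, at percentiles of 1.03, 1.60 and 0.860, where the random pairs had median r of 0.592 to 0.671. The exact test sets each r against no relation and not against these random pairs. With the trend on the number of genes held removed, epiblast with trophectoderm had r = -0.626 (adjusted p = 0.269). The primitive endoderm score had r = 0.786 with the parietal (exact p = 0.0562; rho = 0.262, exact p = 0.536) and r = 0.644 with the visceral endoderm score (exact p = 0.0944; rho = 0.0714, exact p = 0.882). Neither passed (both adjusted p = 0.186), and they lay at percentiles of 89.4 and 76.4 among random list pairs, whose median r was 0.488 and 0.440. Both values rested on blastoid 8, without which r was 0.0724 and -0.265, whereas r was 0.787 and 0.747 without blastoid 2, and -0.0286 and -0.0678 without both. Trophectoderm and junction scores had r = 0.792 (exact p = 0.0254; rho = 0.786, exact p = 0.0279; adjusted p = 0.140), at a percentile of 81.4 among random pairs with median r of 0.628, and r = 0.523 without blastoids 4 and 6. That pair passed without blastoid 3 (adjusted p = 0.0426), without blastoid 5 (0.0415) and with a filter of 5 TPM (0.0471). With the mean of each library pair removed, r was -0.317 for epiblast with trophectoderm, 0.348 for epiblast with primitive endoderm, -0.289 for trophectoderm with primitive endoderm, 0.914 for primitive with parietal endoderm, 0.531 for primitive with visceral endoderm and 0.133 for trophectoderm with junction. Swaps within 4 pairs cannot reach a p of 0.05.

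**Figure D3:**
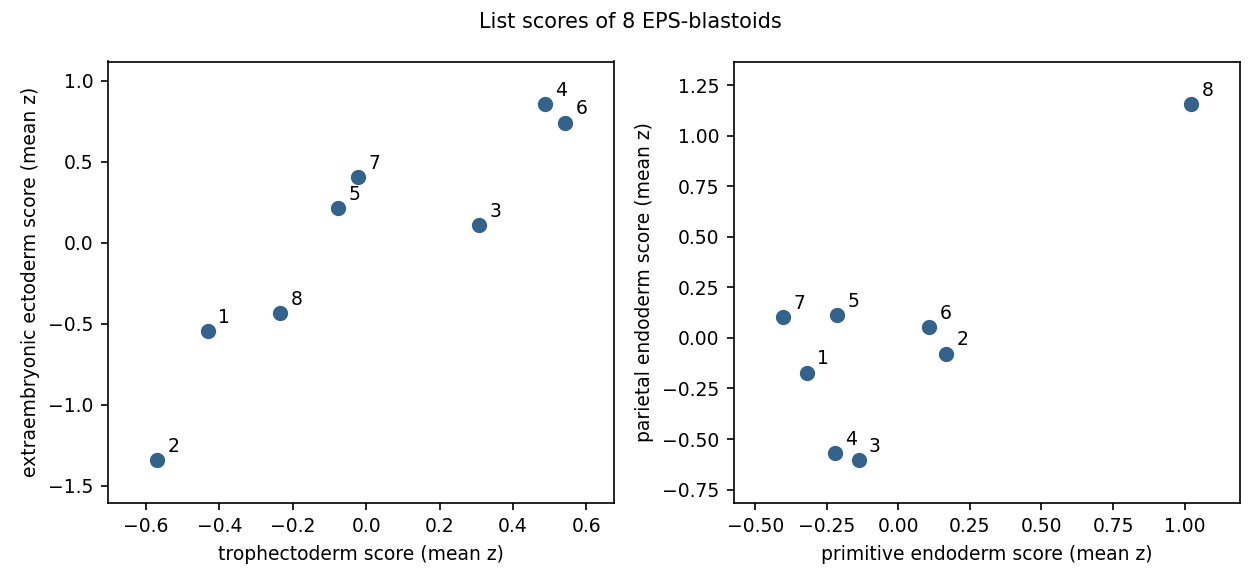
Trophectoderm against extraembryonic ectoderm scores (left) and primitive endoderm against parietal endoderm scores (right), each the mean z-score of log2(TPM + 1), with 1 numbered point per blastoid. The left pair rises together (r = 0.904), and on the right blastoid 8 lies apart at scores of 1.02 and 1.16.

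Relations between single marker genes could be computed for 4 of the 12 planned pairs, because the others included a gene under the filter of 1 TPM. Adjusted p-values are over these 4, which is less strict than the planned adjustment over 12. The planned adjustment was not made. Krt8 and Krt18 had r = 0.276 (exact permutation p = 0.53; rho = 0.143, exact p = 0.752; r = -0.254 without blastoids 3 and 4). Without 1 blastoid it ranged from 0.0233 (without 4; 0.0357 without 2) to 0.625 (without 1). Pou5f1 and Sox2 had r = 0.109 (exact p = 0.949; rho = -0.109, exact p = 0.827; r = -0.178 without blastoids 1 and 3; 0.0227 to 0.219 without 1 of blastoids 1 to 7, the ends being without 3 and without 2). Nanog and Gata6 had r = -0.144 (exact p = 0.875; rho = -0.216, exact p = 1), and no r could be had without blastoids 5 and 6. Nanog and Gata6 each passed 1 TPM in 1 library, not the same, which fixes r near this value, so the pair does not test a relation. Sox2 also passed 1 TPM in 1 library. The adjusted p-value of each of these 3 was 0.949. With the mean of each library pair removed, r was -0.499 for Krt8 with Krt18 and -0.0888 for Pou5f1 with Sox2. Fgf4, a growth factor of the epiblast, and Fgfr2, a receptor for it, passed the threshold (r = 1.00, exact p = 0.00595; rho = 0.969, exact p = 0.00893; adjusted p = 0.0238). That relation rested on blastoid 6, the only library where either reached 1 TPM (24.5 and 30.3 TPM), and the adjusted p was 0.500 with values under 1 TPM set to 0, 0.0952 without blastoid 1 and 0.0714 without blastoid 5.

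No other gene could be tied to a lineage score. With limma, 0 of 11080 genes followed the epiblast score, 0 of 11084 the trophectoderm score and 0 of 11084 the primitive endoderm score at an adjusted p under 0.05. At an unadjusted p under 0.05 the counts were 635, 1120 and 596. Of 100 permuted scores, 10, 4 and 64 gave as many. At an adjusted p under 0.05 with limma, up to 104 genes followed a permuted primitive endoderm score. In simulated data the same fit recovered 44% of genes with a slope of 4 log2 units per SD of the score. At a slope of 2 it recovered 6%. Those slopes were added to each gene's full shuffled spread, whereas a gene that follows a score closely has less spread left over. These rates therefore do not set the weakest relation detectable with 8 blastoids, and relations may have been missed.

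Estimated transcript shares were uniform for Pkm and varied between libraries for the lower genes Dnmt1, Dnmt3a, Dnmt3b, Ctnnd1 and Numb. The leading transcript of Pkm, the pyruvate kinase gene (ENSMUST00000034834, 11 exons, chromosome 9, 59656368 to 59679375), took 94.5 ± 3.39% of the gene's FPKM (n = 8) and led in all 8. For Dnmt1, the maintenance DNA methyltransferase, ENSMUST00000004202 led in 4 of 7 blastoids and ENSMUST00000178110 in 3, with shares of 0% to 99.8% for the former. The leading transcript's share ranged from 0% to 92.6% over 6 blastoids for Dnmt3a (ENSMUST00000172689) and from 0% to 97.1% over 4 for Dnmt3b (ENSMUST00000088976). It ranged from 0% to 100% over 5 for Ctnnd1 (ENSMUST00000111694) and from 0% to 70.0% over 5 for Numb (ENSMUST00000117217). The varying genes averaged from 39.3 TPM (Ctnnd1) to 112 TPM (Numb), against 2058 TPM for Pkm. Loss of transcripts or uncertain assignment of reads to transcripts could therefore not be told from differences between blastoids. Cd44 (ENSMUST00000005218) was at 100% in 2 blastoids, and Fgfr2 (ENSMUST00000120187) at 90.1% in the 1 that held it.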

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

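The tests of explanations in this part were all chosen only after the results were seen. For each of 85 measures, the highest and the lowest of the 8 blastoids were checked for a gap from the nearest other that chance exceeds in about 1 in 20 measures. In 30 measures a blastoid stood apart in this way, 16 of them in blastoid 2, 6 in blastoid 8, 3 in blastoid 1, 2 each in blastoids 5 and 6 and 1 in blastoid 4. That rate does not apply to all of them: 20 of the measures are genes picked for a high spread, and these gave 14 of the 30, 12 of them in blastoid 2, so that number follows largely from the choice of genes. Of the other 65 measures 16 stood apart, 4 in blastoid 2, and genes listed at 0 in most libraries meet the bound easily.

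Blastoid 8 held the most endoderm genes and had the highest sum of visceral endoderm genes (0.0300% of TPM). However, blastoid 2 had higher sums for primitive (0.582% against 0.435%) and parietal endoderm (0.171% against 0.165%), with Pdgfra at 156 TPM and Sparc at 1707 TPM also highest there. Most of its primitive endoderm sum was Apoe at 4558 TPM. The epiblast gene Dppa5a was highest there too, so that sum alone does not show endoderm. The primitive and parietal endoderm scores of blastoid 8 were 1.02 and 1.16, with Gata6 at 28.5 TPM, Srgn at 619 TPM and Ttr at 120 TPM. Chance loss of transcripts elsewhere stays open. Of 24 members of the 3 endoderm lists, 11 were highest in blastoid 8, against a median of 3 in matched random lists. However, these lists were picked because they stood out, and singly none of the 3 passed there. Their lowest adjusted p was 0.611 over 160 pairs of list and blastoid (permutation of list membership). No pair of the 160 passed, but the lowest adjusted p of all, 0.0720, was for other lists. These were epiblast in blastoid 1 (7 of 17 members highest there) and BMP targets in blastoid 5 (4 of 7). Blastoids 4, 5 and 6 held more genes than blastoid 8 (6987, 7436 and 9164 against 5424), so it was not the fullest library. They held at most 10 of the 42 listed members at 1 TPM or more, against 17 in blastoid 8. Since the lists were picked because they stood out there, that count is not a separate test. In blastoid 8, 0 of 15 fibroblast genes reached 1 TPM, which argues against feeder cell RNA. A candidate explanation is that this blastoid held more endoderm cells, but RNA from another structure was not tested, and no biological explanation was tested, since the labels give 1 group.

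Blastoid 2 lacked 9 of 14 trophoblast genes held by most others, with Rhox6 listed at 0 and Cdkn1c at 0.352 TPM. Other trophoblast genes were highest there (Krt7 at 87.4 TPM, Tacstd2 at 505 TPM) or present (Tfap2c at 297 TPM, Krt8 at 2286 TPM). Depth is an unlikely cause, as 3 blastoids with fewer mapped bases held more genes. Loss of transcripts of all kinds may account for part of it, since 29.4% of the 1584 genes held by all 7 others (466 genes) were under 1 TPM in blastoid 2, against 15.9% in blastoid 1 and 8.59% or less in each other. Fewer trophoblast cells and general loss cannot be told apart with 14 genes. Of these, 9 were lost against a median of 6 matched genes (one-sided permutation p = 0.102, adjusted p = 0.817 over 8 blastoids). No other biological explanation was tested.

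Low values were shared within 4 pairs of libraries. Genes at 100 TPM or more in a single library left their highest trace in the partner library in 7 of the 7 libraries with at least 5 such genes, at 2.75 to 9.24 per 10000 there and at most 1.10 elsewhere, which is consistent with reads passed between the libraries of a pair. On average the pairs were also alike in the genes they held. Of the 105 ways to pair the blastoids, 4, the real one included, gave a mean Jaccard index as high (0.455, against a median of 0.407 and a highest other of 0.464). Yet only blastoids 5 and 6 were each other's closest match (0.588). Blastoids 1 and 2 (0.344) lay below the median of all pairs (0.404), 3 and 4 (0.428) below 3 and 7 (0.431), and 7 and 8 (0.460) below 4 and 8 (0.495). The index also depends on the number of genes held, so whether a shared batch or culture contributes stays open. By Spearman's correlation the real pairing was the highest of the 105 (mean 0.688, highest other 0.633), but that measure also ranks the shared low values. Blastoids 1 and 2 had the highest Spearman correlation of all pairs (0.792) but ranked 28 of 28 by Pearson's over genes in all 8 (0.745). Each also had low values with the other blastoids (0.804 to 0.843). That set includes values of the size of traces, such as Swi5 and Psmb3 at 1.06 and 1.16 TPM in blastoid 2 against 1792 and 2220 in blastoid 1. The low rank therefore need not show a difference in level between these blastoids. No biological explanation was tested.

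Other measures in which blastoid 2 stood apart were its S phase score (-0.981), Pdgfra (156 TPM), Utf1 (0.125 TPM) and the imprinted gene Phlda2 (0.758 TPM). Among the most variable genes it stood apart for Arpc2 (0.841 TPM), Slc2a1 (0.443), Swi5 (1.06), Psmb3 (1.16), Chchd2 (0.53), Prr13 (0.995), Tubb6 (0.500), Aprt (0.0310), Anxa1 (0.890) and Eif3k (0.283). Blastoid 1 stood apart for Trf (198 TPM), Atp5g1 (0.105 TPM) and Lamp1 (0.771 TPM). Nanog at 43.2 TPM and Fgf8 at 29.7 TPM set blastoid 5 apart. Gsc at 23.2 TPM and Wnt3 at 10.4 TPM did so for blastoid 6, Sall2 at 19.2 TPM for blastoid 4 and Sox2 at 37.7 TPM for blastoid 8.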

How the results depend on the processing

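The settings that remove the trend on genes held, set values under 1 TPM to 0, leave out blastoids 1 and 2, remove the means of library pairs, compare the SD without its trend or keep genes in all 8 were chosen only after the results were seen. Genes following each score stayed at 0 with limma under all 21 alternatives, with 250 to 976, 430 to 1620 and 226 to 1196 genes at an unadjusted p under 0.05 for the epiblast, trophectoderm and primitive endoderm scores. The count of lineage genes in all 8 and the share of the leading Pkm transcript moved little under all 13 and 9 alternatives run. Across these results, the cause of a change was not tested.

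The number of lists whose members vary together (2) was 1 with FPKM as deposited, 1 with no filter, 4 with the trend on genes held removed, 3 at a filter of 5 TPM (parietal endoderm added), 3 with rank correlation (epiblast and extraembryonic ectoderm added, hypoxia and glycolysis lost) and 1 to 2 without 1 blastoid. The number more variable than matched genes (2) was 1 without blastoids 1 and 2, 3 at pseudocount 0.1 and with median-of-ratios scaling (hypoxia and glycolysis added), 0 with the SD compared without its trend (where the median of mitochondrial genes was -0.17 from that of matched lists) and 1 to 2 without 1 blastoid. Related list scores (1) numbered 0 with median-of-ratios scaling, without the 2 farthest blastoids, with the trend on genes held removed and without blastoids 1 and 2, 2 with no filter and at a filter of 5 TPM, and 0 to 2 without 1 blastoid. Related marker genes (1) numbered 0 at 5 TPM, where only Krt8 with Krt18 could be tested and the passing pair, Fgf4 with Fgfr2, could not. They also numbered 0 with values under 1 TPM set to 0 and without blastoids 1 and 2, and 0 to 1 without 1 blastoid. The median correlation between blastoids (0.467) was 0.549 with no filter, 0.882 over genes in all 8, and 0.432 to 0.502 without 1 blastoid.

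Some correlations of scores changed sign. Epiblast with trophectoderm was 0.0904 at pseudocount 0.1, and epiblast with primitive endoderm was -0.0217 at 5 TPM and -0.00176 without z-scoring. Without the 2 farthest blastoids, primitive with parietal endoderm was -0.0286, with visceral endoderm -0.0678, and G2/M with S phase -0.314. Trophectoderm with YAP targets was -0.341 with the trend on genes held removed. Without blastoids 1 and 2 it was -0.349, trophectoderm with p53 targets -0.176 and G2/M with S phase -0.878. Leaving out 1 blastoid gave -0.358 to 0.131 for epiblast with trophectoderm, -0.115 to 0.261 for epiblast with primitive endoderm, -0.350 to 0.179 for trophectoderm with primitive endoderm, -0.265 to 0.756 for primitive with visceral endoderm, -0.0133 to 0.619 for trophectoderm with YAP targets and -0.675 to 0.744 for G2/M with S phase. The mean correlation of primitive endoderm genes was -0.0288 to 0.163 and that of parietal endoderm genes -0.106 to 0.237. With the means of library pairs removed, the latter was -0.0283, epiblast with FGF-ERK targets -0.0699, Krt8 with Krt18 -0.499 and Pou5f1 with Sox2 -0.0888; no count of passing relations was made there, since swaps within 4 pairs cannot reach the threshold. Of 281 values of single relations under the other alternatives, 248 kept direction and side of the threshold, 12 no longer passed it, 3 newly passed it and 18 changed sign.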

Other observations

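This part gives values with no test of an explanation. Imprinted genes, which are expressed from the copy of 1 parent, were partly expressed. Of 21, 2 reached 1 TPM in all 8 blastoids, 13 in at least 4 and 17 in at least 1. Snrpn, a splicing factor, averaged 272 ± 132 TPM and Igf2r, a receptor that clears IGF2, ranged from 1.31 to 12.8 TPM. Igf2, a fetal growth factor, reached 85.4 to 227 TPM in blastoids 3, 4, 6, 7 and 8 and was under 1 TPM in the other 3. H19, the untranslated RNA next to it, reached 4.09 to 49.8 TPM in blastoids 4 to 7.

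Targets of p53, the DNA damage regulator, had the highest share of gene-by-library values at 1 TPM or more of the signalling lists (67.0%), with 3 of 14 in all 8 blastoids, 10 in at least 4 and 13 in at least 1. Bax, which promotes cell death, averaged 1152 ± 436 TPM and Ccng1, a cyclin, 265 ± 120 TPM. Cdkn1a, the p21 cell cycle inhibitor, reached 344 to 1080 TPM in 7 blastoids and was under 1 TPM in blastoid 2. BMP targets reached 1 TPM in 50% of their gene-by-library values, with Id2 at 458 ± 289 TPM and Id3 at 417 ± 242 TPM. FGF-ERK targets did so in 34.7%, with the feedback inhibitor Spry2 at 390 ± 137 TPM. The share was 31.2% for YAP targets, with Cyr61 at 81.1 to 525 TPM in 4 blastoids and Amotl2 at 40.4 to 166 TPM in 7. It was 15.9% for WNT targets, where Znrf3 reached 12.9 to 75.2 TPM in 6 blastoids, Notum 46.1 TPM in blastoid 4 and Axin2 at most 2.42 TPM, and 14.6% for NODAL targets, where Nodal itself reached 296 TPM in blastoid 1. Stress genes were present at 52.5% for the integrated stress response, with the chaperone Hspa5 at 501 ± 165 TPM, and at 43.8% for immediate early genes, with Fos at 44.8 to 364 TPM in 7 blastoids. The share for hypoxia and glycolysis was 52.2%.

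Cell cycle genes were found in all blastoids. S phase genes reached 1 TPM in 85.2% of their values, with Rrm2, of nucleotide synthesis, at 408 ± 233 TPM and Slbp, which binds histone RNA, at 512 ± 257 TPM. G2/M genes did so in 68.8%, with Ccnb1 at 329 ± 159 TPM, Cdk1 at 200 ± 137 TPM and Birc5 at 521 ± 169 TPM. Mitochondrial genes did so in 97.2%, with mt-Nd2 listed at 0 in blastoids 3 and 4. The remaining pairs of scores did not pass. The epiblast and FGF-ERK scores had r = 0.444 (exact permutation p = 0.264; rho = 0.571, exact p = 0.151; adjusted p = 0.363; r = 0.0630 without blastoids 5 and 6, 0.276 without 3, 0.719 without 7, and -0.0699 with the mean of each library pair removed). The trophectoderm and YAP scores had r = 0.513 (exact p = 0.190; rho = 0.524, exact p = 0.197; adjusted p = 0.299; r = 0.499 without blastoids 4 and 6). This r rested on blastoid 2: it was -0.0133 without it, -0.349 without blastoids 1 and 2 and -0.341 with the trend on the number of genes held removed. The trophectoderm and p53 scores had r = 0.661 (exact p = 0.0795; rho = 0.667, exact p = 0.0831; adjusted p = 0.186; r = 0.428 without blastoids 4 and 6, 0.437 without 2, and -0.176 without 1 and 2). The G2/M and S phase scores had r = 0.614 (exact p = 0.101; rho = 0.238, exact p = 0.582; adjusted p = 0.186; r = -0.314 without blastoids 2 and 4, and -0.675 without 2). Among random list pairs these 4 lay at percentiles of 23.9, 41.6, 68.5 and 58.5.

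The labels call the samples male. Of the 4 Y-linked genes listed, Uty was at 12.3 TPM in blastoid 4, 18.3 in blastoid 7 and 0.774 in blastoid 8, Eif2s3y was at 1.98 TPM in blastoid 4, and Ddx3y and Kdm5d were listed at 0 in all 8. Xist, the RNA that silences an X chromosome in females, was also listed at 0 in all 8. Blastoids 5 and 6, with the most genes held, had all 4 Y-linked genes at 0, and in these libraries no proteasome subunit was under 1 TPM. Whether these zeros go against the labels was not settled.

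Trace values set how far low levels can be read. Of values at 1 TPM or more, 16 in blastoid 1, 4 in blastoid 2 and 3 in blastoid 7 were under 0.2% of the partner library's value, and 0 were in the other 5. Genes above 0 but under 1 TPM made up 27.7% of genes above 0 in blastoid 6 and 55.4% in blastoid 2. The median level of genes at 1 TPM or more was 31.2 TPM in blastoid 6 and 175 TPM in blastoid 2.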
